A study of Mus musculus with 14 samples.

How the data were processed

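The labels describe 14 samples in 10 groups, all from a mouse embryonic stem cell (mESC) hybrid of the Cas and 129 strains or from neural precursor cells made from it. There was 1 sample each for mESC, NPC, 100k.del, 145k.del, 18k.del and bc.del, and there were 2 each for 680kinv, abc.del, ab.del and c.del. Per the labels' protocols, libraries were cut with MboI and enriched with RNA baits for 45488946 to 50879849 on chromosome 16. Whether the 2 matrices used here came from such captured libraries is not given in the sources used here, because no label names an untreated or an auxin-treated sample. The matrices were therefore named by their deposited names, as untreated mESC and as mESC after 2 days of auxin, and no labelled group entered a comparison.

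Per the deposited names, the authors combined replicates, binned the read pairs at 10 kb and balanced the matrix by iterative correction, which removes differences in coverage between bins. The values are contact values without a unit, not scaled to depth. Per the submitters' processing notes, the build was mm10 and Trim Galore was used; the aligner, the read filters and the balancing tool are not given in the sources used here. Each deposited matrix is symmetric with 535 bins from 45520001 to 50870000, taking each bin's stated position as its start. Row sums differ between bins (95.5 to 1905.2 untreated, 113 to 2129.9 auxin); the reason is not given in the sources used here.

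Each value was a whole number of read pairs times a factor for each of its 2 bins. These factors were estimated from pairs over 1500 kb apart, and 100% of nonzero values in the untreated matrix and 99.96% in the auxin matrix came within 0.02 of a whole number. The recovered totals were 439849 and 434813 read pairs, of which 376400 and 373348 linked bins at least 20 kb apart. Pairs per bin ranged from 14 to 4348 and from 19 to 4150, and 18 bins had under 100 pairs in at least 1 matrix. The bin starting at 48140001 held 26 pairs untreated and 560 auxin, and the one at 48960001 held 14 and 392. Single values near these bins, such as for Dzip3 and the boundary bin starting at 48150001, were not repeated without them. In the 2 to 5 Mb range 71.8% and 67.4% of bin pairs were empty, so single distant bin pairs carry little information and means over areas were used.

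Expected contact was the mean value at each distance in the same matrix, and observed over expected contact is called distance-corrected. A rise in some pairs therefore lowers this value for others at that distance. The insulation score was log2 of the mean contact in a square of 100 kb on each side of a bin over its mean across the interval. Boundaries were local minima at least 0.2 below the lower flanking maximum within 250 kb, and shared boundaries lay within 20 kb. Domains were stretches of at least 100 kb between consecutive boundaries. Contacts within domains were divided by those between adjacent domains, from 20 kb apart. Contact at the paired ends of a domain (3 by 3 bins) was divided by that of squares shifted by 50 kb. Compartments came from the first eigenvector of the correlation matrix of distance-corrected contacts in 50 kb bins, oriented by bins covered by protein-coding genes. Compartment strength was contact within the 2 classes over that between them, for pairs over 200 kb apart. The distance decay compared matrices scaled to the same sum.

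Gene positions came from a RefSeq annotation of GRCm38.p6, which has the coordinates of mm10. It placed 22 of the 25 listed genes; Cd200, Zbed2 and Guca1c were not placed and were not analysed here. The annotation table used has no strand, so gene bodies were used where gene starts had been planned. Fixed before the data were examined were the results, their settings, most alternatives, the gene lists (germline and early embryo, resistin-like, lymphocyte and immune surface, other) and the rule for named items. That rule was Dppa2 and Dppa4, the listed genes, and the 5 boundaries with the largest rise and the 5 with the largest fall, with the nearest protein-coding gene within 100 kb. Contacts between whole domains, including those of the Dppa2 and Dppa4 domain, and contacts across a single boundary were added after seeing the data.

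With 1 pooled matrix per condition no test between conditions was possible and no p-value between them was computed. Counting error came from 200 Poisson resamples of the recovered pairs of each matrix, with boundaries, domains and classes held fixed, giving 95% intervals. Pairs amplified from 1 molecule are not independent, and spread between cultures is not covered. Resampling adds noise and lowers correlations, so none of the correlations has an interval. Boundary positions were compared with 10000 random circular shifts. A further reference was 100 random splits of the pooled pairs into 2 matrices that keep each matrix's bin factors and distance decay and have no other difference. Splits said below to be without a difference still differ in these respects.

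The steps were tested on simulated data: 5 simulated matrices of 535 bins with the untreated factors and 19 planted boundaries, each against a second matrix with 9 of them removed. All planted boundaries were found (100%) with 0% false calls, and 100% of nonzero pairs were recovered. The planted ratio of contacts within domains to those between them was 1.87, against 1.19 in the untreated matrix. Boundaries as shallow as those in the data were therefore not tested. Mean insulation change was 0.81 at removed boundaries against a true 0.82. At the kept boundaries it was -0.15 against a true -0.18, so a boundary left in place shifted when others were removed. Mean compartment strength, with the planted classes given, was 1.44 against a true 1.45. Alternatives changed the window, depth, domain source, bin size, scaling, sparse bins and balancing. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.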

Results

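The series studied how contacts around the mouse genes Dppa2 and Dppa4 are organised in a part of chromosome 16 that was examined for elements controlling DNA replication. Dppa2 and Dppa4 encode DNA-binding proteins of pluripotent cells and the early embryo. Hi-C joins DNA ends that lie close together in the nucleus, so that the number of read pairs linking 2 bins measures how often they touch. The labels describe 14 Capture Hi-C samples in 10 groups: mouse embryonic stem cells (mESC), neural precursor cells, and mESC lines with a named deletion or inversion. None of these samples had a matrix of its own here, and comparisons with the deletion, inversion and neural precursor samples were not analysed here. The data were 2 pooled contact matrices, one of untreated mESC and one of mESC after 2 days of auxin. Auxin is a plant hormone used in engineered cells to trigger the degradation of a tagged protein. The labels name neither the auxin treatment nor a tagged protein.

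Each matrix held 10 kb bins from 45520001 to 50870000 on chromosome 16 (mm10). The untreated matrix corresponded to 439849 read pairs and the auxin matrix to 434813, with a median of 1542 and 1532 pairs per bin. With 1 pooled matrix per condition there were no replicates, so every comparison below compares these libraries and not the conditions. Intervals in brackets are 95% intervals from resampling the read pairs and cover counting error only. A value is said to rise or fall from untreated to auxin only where this interval excluded 0 on the log2 scale.

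The question put first here was which regions the Dppa2 and Dppa4 domain touched in each matrix, a comparison of domains added after seeing the data. In the untreated matrix both genes lay in a domain at 48240001 to 48430000, between a pair of called boundaries. Its contacts with the distant Nectin3 side of the interval fell in the auxin matrix. With the domain at 46.44 to 46.65 Mb, which holds part of Nectin3, a cell adhesion gene, distance-corrected contact went from 2.09 to 1.41 times the mean at that distance, a log2 ratio of -0.56 (-0.87 to -0.29). With the domain at 45.97 to 46.43 Mb, which holds Cd96, Gm4737 and parts of Plcxd2 and Nectin3, it went from 1.82 to 1.11 (log2 -0.71, -0.99 to -0.40). On the other side, contact with the Myh15 domain at 49.03 to 49.5 Mb rose from 0.387 to 0.558 (log2 0.53, 0.33 to 0.72). The domains on either side had ratios of the same sign. The one at 48.08 to 48.23 Mb gave -0.55 and -0.73 with these Nectin3-side domains and 0.64 with the Myh15 domain. The Morc1 domain at 48.44 to 48.67 Mb gave -0.33, -0.21 (-0.43 to 0.008) and 0.66. These contacts therefore did not set the Dppa2 and Dppa4 domain apart from its neighbours.

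**Figure D1:**
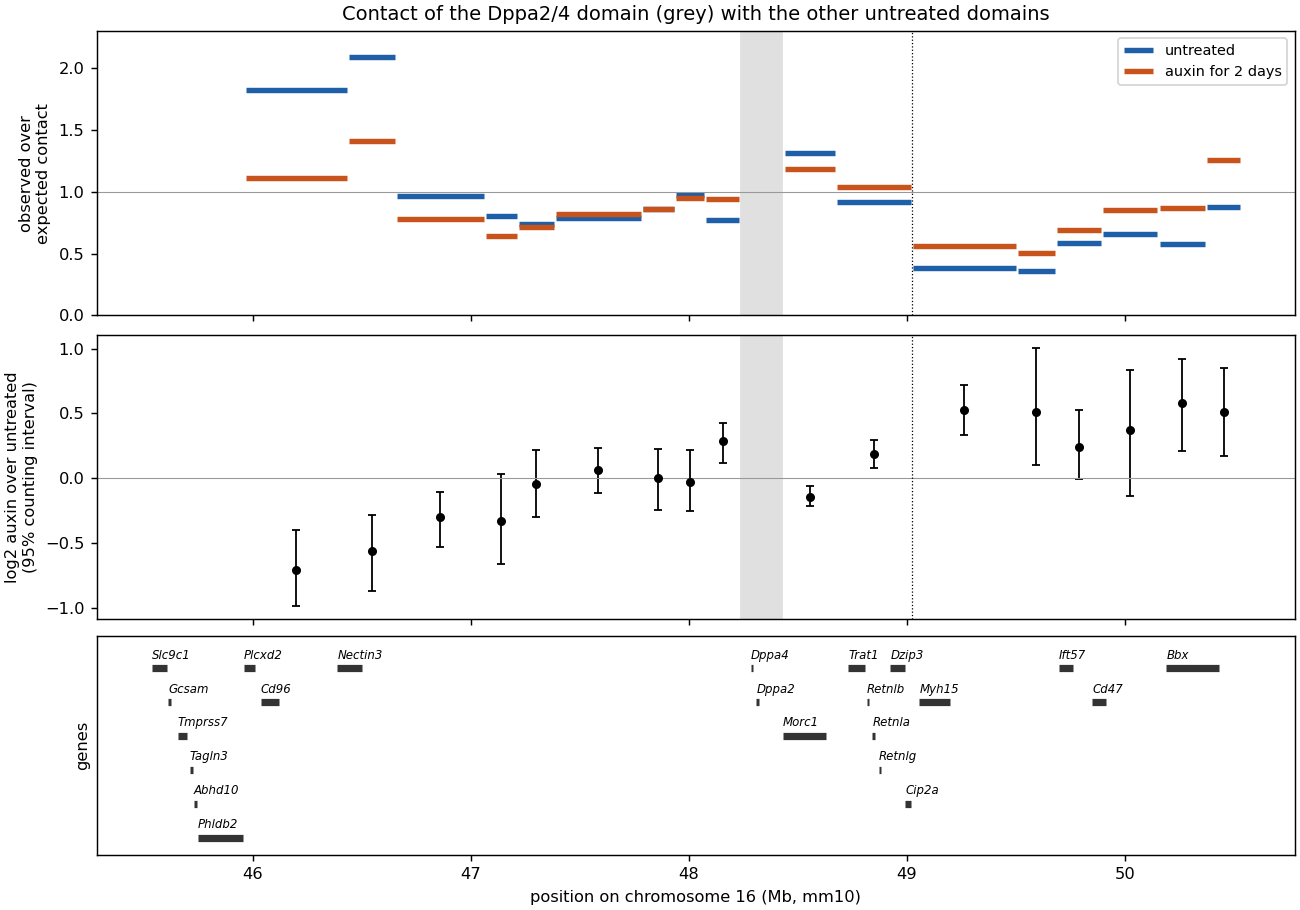
Contact of the Dppa2 and Dppa4 domain with the other 17 domains called in the untreated matrix, by position on chromosome 16 (Mb). The top panel gives observed over expected contact in each matrix (no unit), the middle panel the log2 ratio with 95% counting intervals as bars, and the bottom panel the named genes; the dotted line marks the boundary bin starting at 49020001. The ratio is -0.71 for the domain at 45.97 Mb and 0.53 for the Myh15 domain; next to the grey domain it is 0.28 on the left and -0.14 on the right.

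Of the 17 other domains, contact with the Dppa2 and Dppa4 domain rose for 6 and fell for 4. Beyond the Myh15 domain, it rose for both domains holding parts of Bbx, an HMG-box gene, by log2 values of 0.58 (0.21 to 0.92) and 0.51 (0.17 to 0.85). It also rose for the domain at 49.51 to 49.68 Mb, which holds no protein-coding gene (0.51, 0.10 to 1.01). Nearer by, it rose for the adjacent domain at 48.08 to 48.23 Mb (0.28, 0.12 to 0.42) and for the domain at 48.68 to 49.02 Mb with Trat1, the resistin-like genes, Dzip3 and Cip2a (0.18, 0.08 to 0.29). Both hold a bin with far fewer pairs untreated than auxin, starting at 48140001 and 48960001. Contact fell for the Morc1 domain at 48.44 to 48.67 Mb (-0.14, -0.22 to -0.06). It also fell for the domain at 46.66 to 47.06 Mb, which holds no protein-coding gene (-0.30, -0.53 to -0.11). For the other 7 domains the interval included 0; for the one at 47.07 to 47.21 Mb (-0.33, -0.66 to 0.04) it excluded 0 in a second set of resamples (-0.71 to -0.01), so this domain lies at the limit. The directions for the Nectin3 and Myh15 domains were the same after the matrices were balanced again and after sparse bins were left out.

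For single genes, contact was measured between the bins of each gene body and the 3 bins holding Dppa2 and Dppa4. It could be measured for 20 of the 22 listed genes that were placed, since Dppa2 and Dppa4 are themselves the reference point. It rose for 5 genes and fell for 1. Myh15, a myosin heavy chain gene, rose from 0.278 to 0.676 times the expected contact (log2 1.28, 0.85 to 1.87). Cip2a, which encodes an inhibitor of protein phosphatase 2A, rose from 0.868 to 1.65 (0.92, 0.35 to 1.47), and its neighbour Dzip3, a ubiquitin ligase gene, from 0.632 to 1.18 (0.91, 0.54 to 1.32). Nectin3 fell from 2.71 to 1.74 (-0.63, -1.01 to -0.30).

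Among the germline and early embryo genes, Morc1, which silences transposons in the male germline, was the only one with a measurable contact, and its log2 ratio of -0.07 (-0.24 to 0.12) included 0. Of the 3 resistin-like genes, which encode small secreted proteins, Retnlb rose (1.23, 0.43 to 2.42) on 13 and 34 read pairs. Retnla (0.53, -0.71 to 1.96) and Retnlg (1.01, -0.53 to 2.81) were not distinguishable at this depth, with 14 or fewer pairs in each matrix. Of the 4 lymphocyte and immune surface genes placed, Trat1, which encodes a T cell receptor adaptor, rose (0.39, 0.04 to 0.67). Cd47, a ligand that restrains phagocytes, had a ratio of 0.68 (-0.06 to 1.51), Cd96 one of -0.61 (-1.42 to 0.24) and Gcsam one of 0.97 (-0.58 to 3.26). These 20 intervals were not adjusted for their number.

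Within the Dppa2 and Dppa4 domain, 21.7% (20.8 to 22.9) of its contacts over 20 kb stayed inside in the untreated matrix and 19.4% (18.5 to 20.5) in the auxin matrix. The log2 ratio was -0.16 (-0.28 to -0.07), and -0.25 when only contacts over 50 kb were counted. The domain did not stand apart from the rest: 16 of the 17 other domains also had a lower share, with a median of 23.7% untreated and 21.7% auxin. The pooled pairs were also split at random into 2 matrices that differed only in bin factors and distance decay, with domains drawn in the first. The log2 ratio then had a median of -0.10 (-0.24 to 0.01 over the splits), and 13 of 100 splits were at least as low as observed. With the domain drawn in a random subset of the untreated pairs and measured in the rest, the log2 ratio averaged -0.16 and was below 0 in all 99 draws that gave one. The share is not distance-corrected, so all these log2 ratios include the difference in distance decay. The whole contact profile of the 3 Dppa2 and Dppa4 bins correlated between the matrices with r = 0.87 (Spearman rho 0.64) across bins before distance correction, below all 100 random splits (lowest 0.88, median 0.92). After distance correction r was 0.39 (rho 0.34), against a median of 0.46 in the random splits, of which 7 were at or below the observed value. Bins are neighbours and not independent replicates.

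The second question was whether the boundaries between domains kept their insulation, the local drop in contacts that pass over a bin. At the left edge of the Dppa2 and Dppa4 domain, the boundary bin starting at 48230001, 43.7 kb from Dppa4, weakened by 0.37 on the log2 insulation scale (0.20 to 0.58). At its right edge, the bin starting at 48430001 had a change of -0.007 (-0.17 to 0.18). Neither edge had a boundary called in the auxin matrix within 20 kb. The bin starting at 48670001, 39.1 kb from Morc1, weakened by 0.24 (0.13 to 0.37). The bin starting at 49500001, 87.3 kb from Gm4802, weakened by 0.37 (0.25 to 0.49). The boundary bin starting at 49020001, between Cip2a and Myh15, was the deepest in both matrices and had a change of -0.002 (-0.18 to 0.19). Random splits of the pooled pairs gave a single rise as large as 0.37 in 8 of 100 cases. By a limit set after seeing the values, 3 untreated boundaries rose by more than 0.3, and 0 of 100 splits had as many. Among these 3, the bin starting at 46650001 lies next to one with 18 pairs untreated and 19 auxin.

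**Figure D2:**
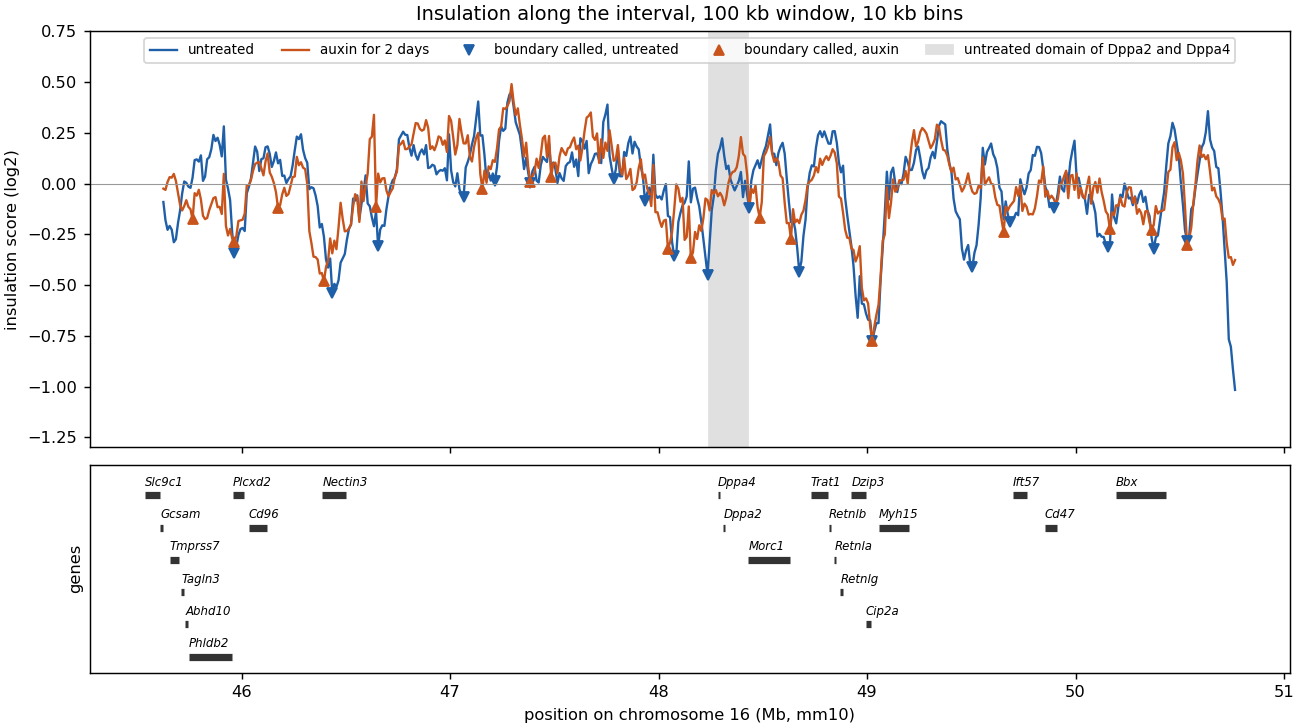
Insulation score (log2, lower is stronger insulation) along chromosome 16 (Mb) in the untreated and auxin matrices, with called boundaries as triangles and gene bodies below. The line of the auxin matrix lies above the untreated one at the left edge of the grey Dppa2 and Dppa4 domain, where the score went from -0.45 to -0.08, and both lines meet at -0.78 in the bin starting at 49020001.

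Across the interval, 19 boundaries were called in the untreated matrix and 17 in the auxin matrix, and 7 of the untreated ones had an auxin boundary within 20 kb. These counts followed the window: 50 and 200 kb gave 38 and 6 untreated, 33 and 5 auxin, and 16 and 1 shared boundaries. At the main settings, random circular shifts of the untreated positions gave a mean of 3.12 shared boundaries. Random splits of the pooled pairs without a difference gave a median of 10, and 4 of 100 splits gave 7 or fewer. The mean change at the 19 untreated boundaries was 0.15 (0.10 to 0.19), at percentile 99.8 of 10000 random shifts. These shifts do not share the choice of low untreated scores, and random splits without a difference gave a median of 0.07 and at most 0.10. The score was higher at 16 of them, and it rose at 5 and fell at none. Of the 5 boundaries with the largest rise, the bin starting at 46650001 rose by 0.36 (0.02 to 0.77) and the one at 47060001 had a change of 0.26 (-0.005 to 0.53). Neither had a protein-coding gene within 100 kb. The bin next to the first, starting at 46640001, held only 18 pairs untreated and 19 auxin. That bin was called as a boundary in the auxin matrix and had a change of 0.02 (-0.10 to 0.15), so the rise at 46650001 was not seen there.

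The largest falls were all at boundaries called in the auxin matrix alone. They were the bins starting at 48150001, within 100 kb of Gm52257 (-0.28, -0.55 to -0.07), at 47150001 (-0.26, -0.49 to -0.02), at 48480001 in Morc1 (-0.24, -0.43 to -0.03), at 46170001 near Gm4737 (-0.22, -0.40 to -0.03) and at 46390001 in Nectin3 (-0.22, -0.41 to -0.05). The bin next to the first of these, starting at 48140001, held 26 pairs untreated and 560 auxin. At all 17 auxin boundaries the mean change was -0.09 (-0.13 to -0.06), at percentile 0.42 of the random shifts, since a boundary called in one matrix is chosen for a low score there. Over all 32 boundaries called in either matrix it was 0.04 (0.002 to 0.07), and 3 of 100 random splits gave as much. Calling boundaries in a random subset of the untreated pairs, with each pair kept at equal odds, and measuring them in the remaining pairs gave a mean change of 0.09, above 0 in 100 of 100 draws. The same procedure on the auxin pairs gave 0.00, above 0 in 53 of 100 draws. This procedure was chosen after seeing the data.

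Of the named genes, the insulation score over the gene body rose for 2 and fell for 6. The windows of neighbouring genes overlap, as for Dppa2 with Dppa4 and Tagln3 with Abhd10, so these genes are not independent. Tmprss7, a membrane protease gene, rose by 0.25 (0.17 to 0.35) and Nectin3 by 0.09 (0.01 to 0.18). The Nectin3 value averages opposite changes within the gene. The untreated boundary bin starting at 46430001 changed by 0.19 (0.05 to 0.35) and the auxin boundary bin starting at 46390001 by -0.22 (-0.41 to -0.05). The score fell at Dppa2 (-0.24, -0.43 to -0.08) and at Dppa4 (-0.22, -0.38 to -0.07), the bins inside the domain whose left edge had weakened. It also fell at Phldb2 (-0.21, -0.27 to -0.15), Trat1, Tagln3 and Abhd10. Contacts inside domains exceeded those between adjacent domains by a ratio of 1.19 (1.16 to 1.21) untreated and 1.09 (1.06 to 1.11) auxin, a log2 ratio of -0.12 (-0.16 to -0.08). None of 100 random splits without a difference was as low (lowest -0.08). With domains drawn in the auxin matrix the log2 ratio was 0.04 (0.005 to 0.08). With domains drawn in a random subset of the pairs and measured in the rest, it averaged -0.13 for untreated domains, below 0 in 100 of 100 draws, and -0.007 for auxin domains, below 0 in 55. Contact between the paired ends of a domain was 1.04 (0.93 to 1.19) times that of nearby squares untreated and 1.12 (0.95 to 1.28) auxin, and the log2 ratio of 0.11 (-0.17 to 0.37) was not distinguishable from 0 over 18 domains.

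The last question was how the interval divided into larger compartments. The first eigenvector of the untreated matrix changed sign near the boundary between Cip2a and Myh15, apart from the single bins at 45.52 Mb, with part of Slc9c1, and at 50.62 Mb. Dppa2, Dppa4, Nectin3 and Morc1 lay on the negative side, and Myh15, Ift57, Cd47 and Bbx on the positive side. In the auxin matrix 15 bins of 50 kb went from negative to positive and 1 the other way. The number of the 22 placed genes with a positive value went from 5 to 12. Dppa2 and Dppa4 went from -0.074 to 0.005 and Nectin3 from -0.052 to 0.025. None of the 8 genes that became positive had a counting interval above 0 in the auxin matrix, so these single changes of sign were not resolved. Slc9c1 went the other way, from 0.016 (-0.010 to 0.040) to -0.10 (-0.12 to -0.039). The resistin-like genes and Trat1 stayed negative in both.

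**Figure D3:**
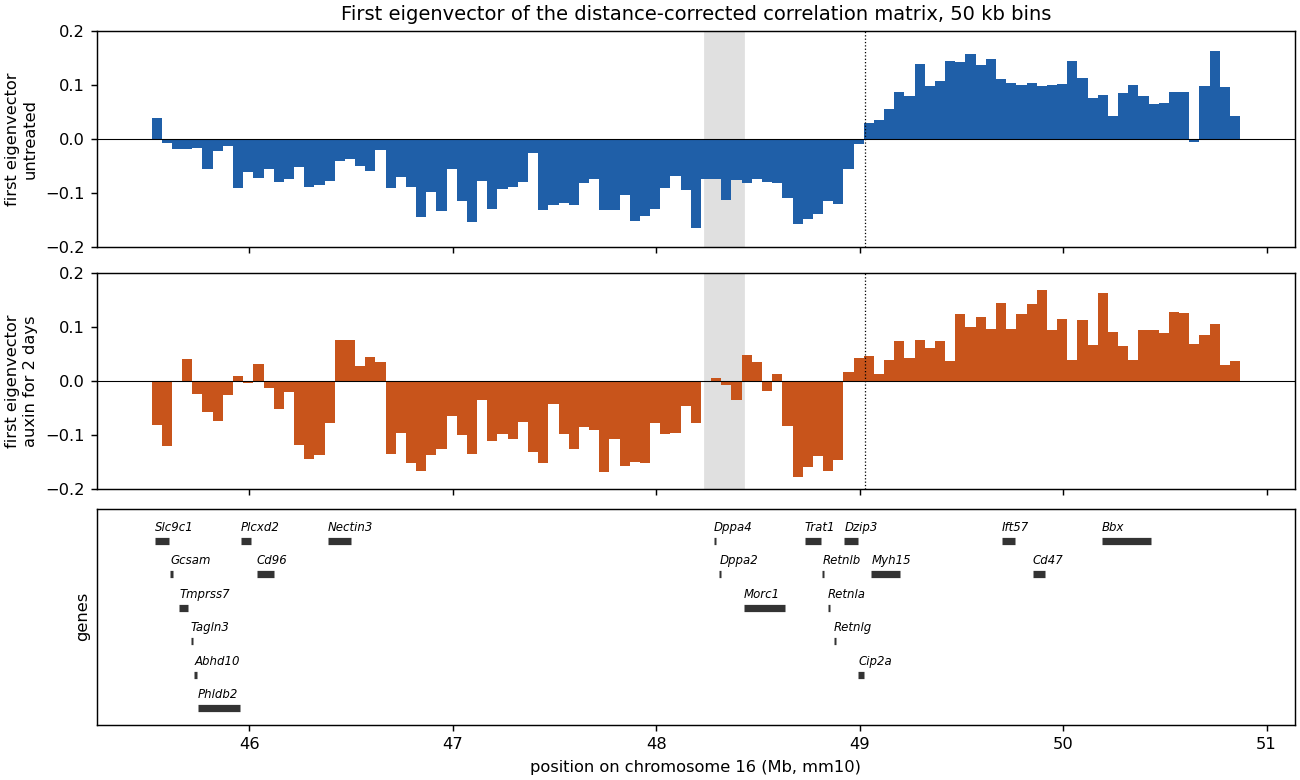
First eigenvector (no unit) in 50 kb bins along chromosome 16 (Mb) for the untreated matrix (top) and the auxin matrix (middle), with named genes below. The grey band is the Dppa2 and Dppa4 domain and the dotted line the boundary bin starting at 49020001; the untreated vector changes sign near that line and in single bins at 45.52 and 50.62 Mb, and 15 bins that are negative untreated are positive in the auxin matrix.

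The 2 eigenvectors correlated with r = 0.83 (Spearman rho 0.85) across 50 kb bins, against a lowest r of 0.91 in 100 random splits. Of the summed absolute eigenvalues of the correlation matrix, with its mean subtracted, the first made up 18.8% untreated and 10.7% auxin. Contacts within the 2 untreated classes exceeded those between them by a ratio of 1.55 (1.52 to 1.58) untreated and 1.19 (1.17 to 1.21) auxin, a log2 ratio of -0.38 (-0.42 to -0.34). Contact between the classes rose from 0.777 to 0.909 of the expected level. Apart from the single bins at 45.52 and 50.62 Mb, the untreated classes are the 2 sides of the boundary between Cip2a and Myh15. Compartment strength here therefore mostly compares contacts on each side with contacts across that boundary. With classes from the auxin matrix the log2 ratio was smaller, at -0.13. The sign of the eigenvector was set by gene-covered bins, which it followed weakly (r = 0.08 untreated and 0.22 auxin), so that neither class is named active or inactive.

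**Figure D4:**
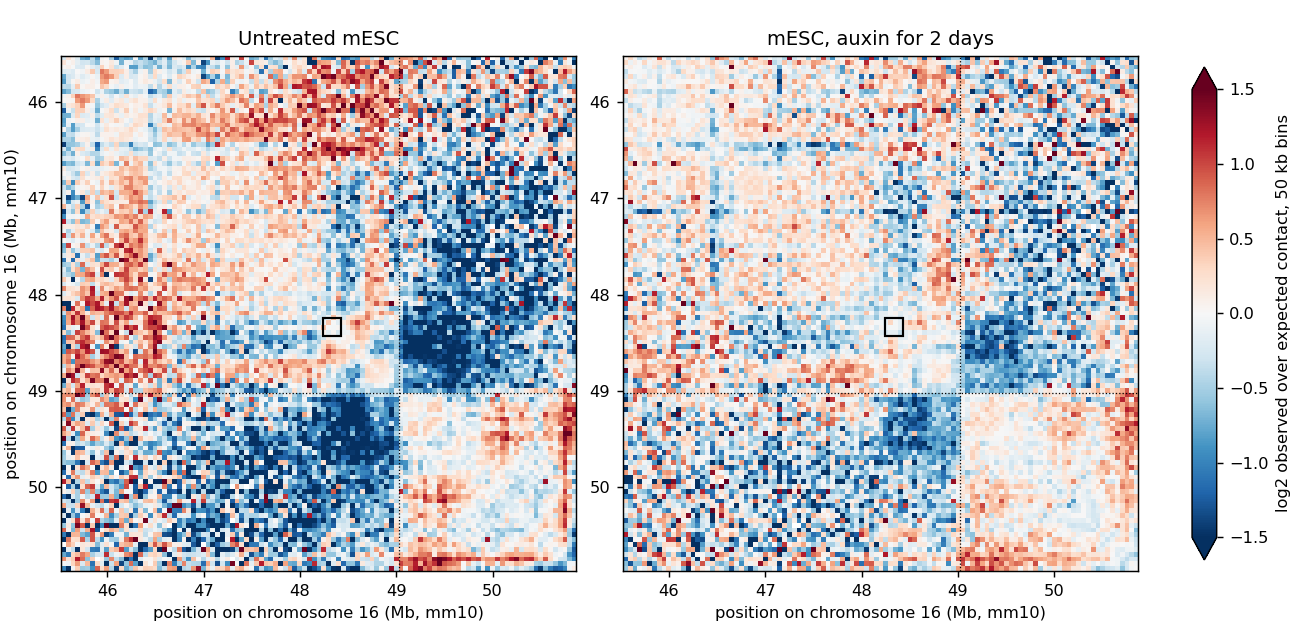
Observed over expected contact (log2, colour) between 50 kb bins of the interval on chromosome 16 (both axes in Mb) in the untreated and auxin matrices; bin pairs with no contact have the lowest colour or none. The square marks the Dppa2 and Dppa4 domain and the dotted lines the boundary bin starting at 49020001; contact between the areas left and right of that line is less depleted in the auxin matrix, with class-to-class contact of 0.909 against 0.777.

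The decay of contact with distance was shallower in the auxin matrix. With both matrices scaled to the same sum, pairs 20 to 100 kb apart fell (log2 -0.10, -0.12 to -0.08), as did pairs 100 to 250 kb apart (-0.06, -0.08 to -0.04). Pairs 250 to 500 kb apart had a ratio of 0.00 (-0.02 to 0.02) and pairs 500 to 1000 kb apart one of 0.03 (-0.0009 to 0.06). Pairs 1000 to 2000 kb apart rose by 0.12 (0.09 to 0.14) and pairs 2000 to 5000 kb apart by 0.23 (0.19 to 0.26), a factor of 1.17. With values as deposited, not scaled to the same sum, pairs 100 to 250 kb apart no longer fell (-0.010, -0.033 to 0.010), and pairs 250 to 500 kb (0.05, 0.03 to 0.08) and 500 to 1000 kb apart (0.08, 0.04 to 0.12) rose. At 500 to 1000 kb the ratio was 0.065 after balancing again and 0.12 with band medians, and medians gave 0.49 at 1000 to 2000 kb. The most distant band rested on 24330 and 27402 read pairs.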

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

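Leaving out bins with under 100 pairs, and calling in a random subset of the untreated pairs, were chosen after seeing the data, as were all alternatives for the Nectin3 and Myh15 domains and for contacts across the Cip2a and Myh15 boundary. Of the values under an alternative, 76 stayed within the counting interval's size (for counts, within 1.5 times), 31 moved and 1 reversed. The cause was not tested. A change of sign counted as reversed only where the main interval excluded 0. The log2 ratio for paired domain ends, 0.11 in the main setting, ran from -0.16 with auxin domains to 0.18 with domains of at least 200 kb. The ratio at 250 to 500 kb, 0.003 in the main setting, was -0.014 without the 10% of bins with most zeros and 0.054 as deposited. The within-domain ratio reversed, from log2 -0.12 to 0.043, with domains from the auxin matrix.

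The mean insulation change at untreated boundaries stayed above 0 throughout; it was 0.20 with a 50 kb window, 0.23 with a 200 kb window and 0.095 when called in a random subset of the pairs. Boundary counts followed the window and depth. Untreated boundaries numbered 38 (50 kb window), 6 (200 kb) and 8 (depth 0.4); auxin boundaries numbered 33, 5 and 6, and 27 at depth 0.1. Shared boundaries numbered 16 (50 kb), 1 (200 kb), 11 (depth 0.1), 2 (depth 0.4) and 11 (within 40 kb).

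The eigenvector correlation was 0.73 in 20 kb bins, and the log2 strength ratio was -0.13 with auxin classes. For the distance decay, values as deposited gave -0.052, -0.010, 0.054, 0.081, 0.17 and 0.28 from the nearest to the most distant band. Band medians gave -0.14, -0.038, 0.024, 0.12 and 0.49 for the first 5 bands; the last had a median of 0 and gave no value. Balancing again gave -0.13 at 20 to 100 kb and 0.065 at 500 to 1000 kb. Contacts across the Cip2a and Myh15 boundary had a log2 ratio of 0.39 after balancing again.

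Depth limits the genes with few pairs, such as Retnla and Gcsam, and single distant bin pairs.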

Other observations

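Contacts across the boundary bin starting at 49020001, between Cip2a and Myh15, those of the Nectin3 side and the right end of the interval were examined only after their values were seen. The boundary's own insulation score was the same in both matrices at -0.78, yet contacts passing over it between bins 250 to 2000 kb apart rose from 0.582 (0.569 to 0.597) to 0.794 (0.782 to 0.809) of the expected level, a log2 ratio of 0.45 (0.41 to 0.49). Nearly all of these contacts also lie between the untreated classes, so they are not a separate observation from the lower compartment strength. Among the 72 pairs of untreated domains on opposite sides of this boundary, contact rose for 35 and fell for 0. Counting error alone would give 3.6 pairs with an interval excluding 0. No random splits were compared for these pairs, so this is not a test. Among the other 81 pairs contact rose for 12 and fell for 31, so that over all pairs it rose for 47 and fell for 31. The correction for distance makes a rise across the boundary lower the values on either side of it. Part of these falls was therefore set by the rise. The Morc1 domain and the Myh15 domain were one such pair, from 0.302 to 0.478 (log2 0.66, 0.51 to 0.86).

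The 2 domains from 45.97 to 46.65 Mb around Cd96 and Nectin3 were compared with the 8 domains between 46.66 and 48.43 Mb. Contact fell for 15 of these 16 pairs and rose for 0, with a median log2 ratio of -0.52. All of them lie left of the Cip2a and Myh15 boundary, so the same limit of the distance correction applies. The pair at 46.44 to 46.65 and 47.07 to 47.21 Mb fell most, from 1.17 to 0.685 (-0.77, -1.04 to -0.45). Domain pairs share bins and are not independent. At the right end of the interval, the last bin with an insulation score, starting at 50760001 and beyond Ccdc54, went from -1.02 to -0.38, a change of 0.64 (0.49 to 0.79). It had no right flank and could not be called as a boundary.

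Weaker insulation at untreated boundaries was weighed with random splits and by leaving out bins with few read pairs, the latter an alternative chosen after seeing the data. Choosing boundaries in one noisy matrix gave at most 0.103 in 100 splits without a difference, with a median of 0.07, against the observed 0.15. With counting noise alone, this choice may account for part of the change but did not give all of it. The splits do not model duplicate pairs or spread between cultures, so they cannot exclude this choice as the cause. Leaving out those bins gave 0.153 (0.12 to 0.18), which argues against few read pairs as the cause. A difference between batches, clones or pooled replicates cannot be told apart from auxin with 1 matrix per condition, and no biological explanation was tested.

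Lower compartment strength was weighed next. A uniform background of random ligations would raise distant contacts and flatten the classes. The constant that removes the excess at 2000 to 5000 kb was 17.8% of the auxin mean there. Subtracting it left a log2 strength ratio of -0.357 (-0.40 to -0.31), so a background of this size is unlikely to be the whole cause. The constant assumes that, without background, the auxin matrix had the untreated ratio of these distant contacts to those up to 1000 kb. A larger background was not tested. Contacts across the Cip2a and Myh15 boundary kept a ratio of 0.43 after this subtraction. They overlap with contacts between the classes, so this is not an independent observation. Batch, clone or replicate differences stay open with 1 matrix per condition. No biological explanation was tested.

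Whether insulation was kept at some boundaries and lost at others was not resolved: the SD of the change over 19 boundaries was 0.13, and counting error alone gave one as large in 26 of 200 resamples. That boundaries at steps of the untreated eigenvector keep their insulation was tested by rank correlation of the change with the step, which gave rho = 0.0842 (permutation test, two-sided, p = 0.732, adjusted 0.732 over 2 tests). Rank correlation of the size of change with read coverage gave rho = 0.135 (permutation p = 0.578, adjusted 0.732). Both values lie within their spread for 19 boundaries, so neither a compartment step nor coverage can be told apart from no relation as a candidate explanation.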
